A study of Mus musculus with 3 samples.

How the data were processed

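MCRS1 was profiled by chromatin immunoprecipitation and sequencing in HT cells, a wild-type mouse pancreatic cancer line. There were 2 immunoprecipitated replicates and 1 input sample of genomic DNA, and the groups and replicate numbers were taken from the sample titles. Per the labels' protocols, chromatin was cross-linked with formaldehyde, sheared by sonication, and precipitated with an antibody against MCRS1. Per the submitters' processing notes, fastp 0.22.0, Bowtie2 2.5.0, MACS2 2.2.7.1 and deepTools 3.5.1 were used with the mouse genome GRCm38. The aligner options, the caller options, and whether the input served as the caller's control are not given in the sources used here.

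Each replicate had its own list of broad peaks, so the authors called peaks per sample and not on pooled reads. For each peak, the authors deposited a fold enrichment, which is a linear ratio to the caller's background averaged over the peak. They also deposited a −log10 p-value and a −log10 q-value. The deposited score is 10 times −log10 p rounded down for 99.997% of the peaks of replicate 1 and 99.995% of those of replicate 2, so it was not used further. No deposited −log10 p lay below 1.00 in either list, and −log10 q was 0 for 99.8% and 99.9% of the peaks. The lists therefore hold regions down to a lenient p, and not a set passing a false discovery rate. Fold enrichments were used only to describe, rank or filter peaks within their own list. Read depth is unknown from these lists, and no interval that needs it is given. Signal tracks and the input sample were not analysed here.

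Genes came from a table of RefSeq gene models on the same build, which gives the start and end of each gene but no strand, exon or sequence. The planned windows on transcription start sites were therefore replaced by windows of 1000 bp on each side of both ends of each gene, called gene ends below. The windows thus take in the ends of transcription as well as the starts, and exon, intron or UTR positions are not given. The planned tests that need sequence, namely promoter motifs and lists matched on CpG content, were not run. Lists matched on local peak coverage took the place of the latter. Analyses used chromosomes 1 to 19 and X, with 21627 protein-coding genes.

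Peaks were called shared when the overlap was at least 50% of the shorter peak. Chance was measured with 1000 circular shifts of the peaks along each chromosome, which keep widths and spacing. A second measure moved all peaks of a chromosome together by 10 to 100 kb in either direction, which also keeps the regional density of peaks. Neither kind of shift left out sequence in which no peak can be called. The smallest one-sided p that 1000 shifts allow is 0.000999. Share of peaks at gene ends, genes with a peak in both replicates, and shared peaks were each compared with these shifts by one-sided permutation tests. The share of each of 37 gene lists with a peak in both replicates was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 37 lists. Each share was also set against 10000 random lists matched on decile of peak coverage within 500 kb and on gene length below 2000 bp, and against the local shifts. Members of a gene cluster share peaks and are not independent. The fold rank of a list was the median over its members of the mean percentile of the highest fold at a gene end, tested by permutation with 10000 random sets. Peak density was given per Mb for each chromosome, and coverage per 1 Mb bin was split into segments at least 5 Mb long whose levels differ at least 1.5 times, found in replicate 1 alone.

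Before the data were examined, the design, the gene lists and the rule for named genes were fixed. The rule took Mcrs1, Yy1, H2-K1, H2-D1, B2m, Tap1, Tap2, Tapbp, Psmb8, Psmb9, Nlrc5 and Irf1 in all cases, and the 10 genes with the highest mean percentile of fold. It also took up to 3 members with a peak in both replicates and 3 with none in each list, and the 5 peaks of highest fold in each replicate. The text gives genes from this set, and says where a locus was chosen otherwise. A peak present or absent at a single gene was not tested against the peak coverage of its region. The alternatives tried were stricter limits on q, p, fold or peak number, other overlap rules, other window sizes, other measures of chance, other ranks, and each replicate alone.

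The labels do not say whether the replicates came from separate cultures, so the 2 lists may differ only technically. The p-values measure how peak positions compare with shifted positions, not variation between cultures. Beside any overlap of the lists stands the possibility that both were called against the same input, which would give them common noise. On simulated lists, the overlap test called 0 of 20 unrelated pairs and 20 of 20 with 5% of the peaks planted on the other list. The gene end test called 2 of 20 lists with nothing planted and 20 of 20 with 2% of peaks planted. Fisher's exact test called 2 of 100 unplanted lists of 20 genes and 100 of 100 with 12 members planted. The overlap and gene end runs were set against local shifts only, and used fewer shifts than the tests on the real lists. The unrelated pairs do not stand for lists with common noise from a shared input, so their rate does not cover that case. The Fisher runs do not cover large families lying in clusters. They used no adjustment over lists, and members besides the 12 planted kept their chance peaks. The planted runs therefore do not show the power for smaller differences. These rates therefore do not give the error rates of the tests on the real lists. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.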

Results

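HT cells, a mouse pancreatic cancer line, were profiled for the genomic positions of MCRS1, a subunit of the INO80 remodelling complex and the NSL acetyltransferase complex. The series title names sensitivity to T cell immunity as its subject, so genes of antigen presentation were examined first among the gene groups. The data comprised 366719 peaks in replicate 1 and 240786 in replicate 2, and 1 input sample was not analysed here. On the chromosomes used, peaks covered 18.95% and 10.26% of the 2571 Mb spanned. The median peak was 976 bp wide in replicate 1 and 862.5 bp in replicate 2. The median fold enrichment, as the authors deposited it, was 1.56 and 1.67, and 0.664% and 2.06% of peaks reached a fold of 2. The median peak had a caller p of 0.0641 in replicate 1 and 0.0408 in replicate 2. Only 10 peaks of replicate 1 and 30 of replicate 2 had a −log10 q of at least 1.

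The highest-fold peak of replicate 1 lay inside Deptor, which encodes an mTOR inhibitor, at chromosome 15, 55160641 to 55161059, with a fold of 3.55. The next highest peaks of replicate 1 lay inside Cadps2 (chromosome 6, 23479434 to 23482015, fold 2.79), 13730 bp from Rnf217 (chromosome 10, 31487589 to 31488156, fold 2.79), 123728 bp from the pseudogene Gm5696 (chromosome 1, 22154344 to 22155323, fold 2.76), and inside Gm10354 (chromosome 5, 14977859 to 14979239, fold 2.73). In replicate 2 the highest peak lay inside the non-coding gene Gm32857 (chromosome 14, 44277637 to 44277924), with a fold of 2.78. It was followed by peaks 1558 bp from Gm18737 (chromosome 17, 37857670 to 37859198, fold 2.75), inside Gm14413 (chromosome 2, 177157107 to 177158727, fold 2.65), 19096 bp from Cpe (chromosome 8, 64572973 to 64573445, fold 2.63), and inside Dync2h1, a ciliary dynein gene (chromosome 9, 7066270 to 7067279, fold 2.63). None of these 5 peaks of replicate 2 reached a −log10 q of 1, the highest being 0.197. Of the 5 of replicate 1, only the Deptor peak did, at 2.71, and the next highest was the Gm10354 peak, at 0.595.

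Peaks of the replicates coincided slightly more often than shifted peaks did. The shifts did not leave out sequence where neither list can have a peak, so a small excess need not come from shared binding. Of the replicate 1 peaks on the chromosomes used, 79171 (21.6%) were shared with replicate 2, against 18.4% for peaks shifted along the chromosome and 19.5% for peaks shifted locally. Of the replicate 2 peaks, 82444 (34.2%) were shared, against 28.7% and 30.8%. The observed share was 1.18 and 1.19 times that of the chromosome-wide shifts, and 1.11 times that of the local shifts in each replicate (one-sided permutation test, p = 0.000999 in each case, the smallest that 1000 shifts allow). Among peaks with a −log10 p of at least 2, a limit chosen after seeing the data, 74 of the 2811 peaks of replicate 1 were shared, 6.32 times the chromosome-wide chance and 3.87 times the local chance (permutation test, p = 0.000999). Of these 74 peaks, 35 lay at only 10 loci, some of them in repeated regions, so the higher ratios need not apply across the genome. Too few peaks passed a −log10 q of 2 for an overlap test, with 1 shared peak among 6 and 17.

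Chromosomes differed several-fold in peak density, and both replicates ranked them similarly. Chromosome 3 carried the most peaks, 193 per Mb in replicate 1 and 184 per Mb in replicate 2, which is 1.18 and 1.97 times the median autosome. Chromosome 14 carried the fewest, 73.8 and 27.1 per Mb, or 0.451 and 0.291 times the median autosome. Chromosomes 4, 7, 10 and 13 were also low, with 85.9, 88.2, 76.1 and 77.6 peaks per Mb in replicate 1 and 34.9, 34.8, 28.6 and 29.6 in replicate 2. Over the 20 chromosomes, the densities of the replicates correlated with r = 0.944 and rho = 0.892 (permutation test, two-sided, p = 1e-05 for each, the smallest the resampling allows, adjusted p = 3e-05 over 3 relations). Without the 2 chromosomes farthest from the median, r was 0.927. Density was not detectably related to protein-coding genes per Mb, with r = −0.142 and rho = −0.277 in replicate 1 (permutation p = 0.551 and 0.237) and r = −0.0829 and rho = −0.0812 in replicate 2 (permutation p = 0.727 and 0.733), the adjusted p lying between 0.356 and 0.733.

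Within 5 chromosomes the density changed in sharp steps. On chromosome 2, peaks covered 7.24% of the part from 4 to 124 Mb in replicate 1 and 28.4% of the part from 124 to 182 Mb, and in replicate 2 they covered 2.49% and 19.7%. The first part of chromosome 8, from 4 to 20 Mb, was the most densely covered segment, at 65.0% and 33.3%, against 23.9% and 16.0% in the rest. On chromosome 9, the part from 4 to 21 Mb had 45.0% and 24.5%, and the rest 8.99% and 3.09%. On chromosome 11 the part from 58 to 77 Mb was low (8.32% and 3.06%) and the part from 99 to 121 Mb high (42.5% and 31.4%). On chromosome 12 the part from 30 to 95 Mb had 8.70% and 3.002%, between flanks of 33.6% and 33.2% in replicate 1 and 18.5% and 20.6% in replicate 2. The 28 segments, drawn from replicate 1 alone, accounted for 76.4% of the variance of the 1 Mb coverage of replicate 2. Each chromosome other than these 5 formed 1 segment, so this share includes differences between whole chromosomes and not only the steps.

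**Figure D1:**
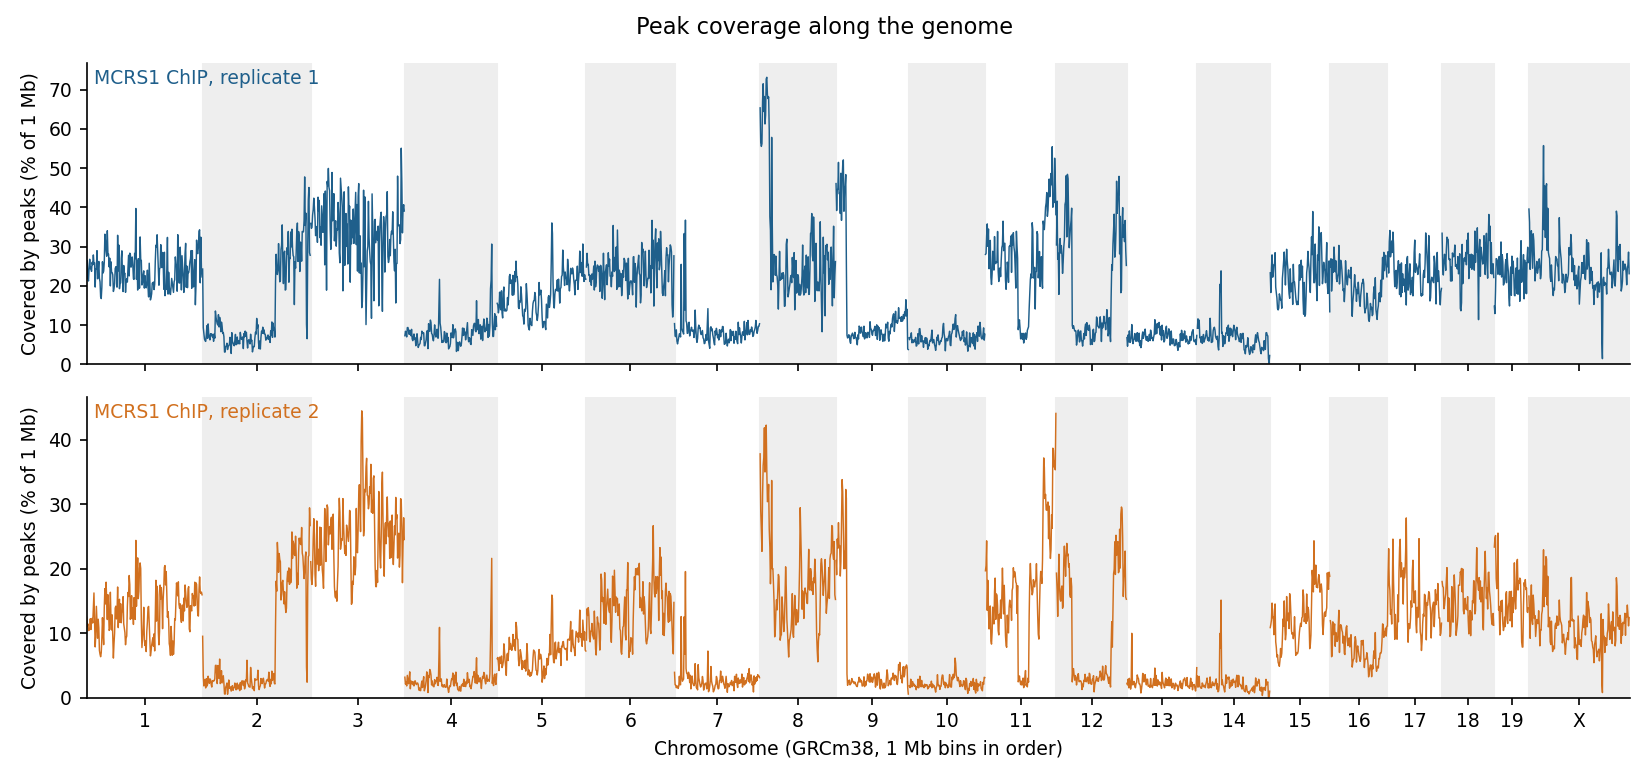
Share of each 1 Mb bin covered by MCRS1 peaks (%), in genome order (GRCm38), for replicate 1 (top) and replicate 2 (bottom), with alternate chromosomes shaded. The first part of chromosome 8 stands highest in replicate 1 (65.0% on average), and both replicates step down and up at the same places on chromosomes 2, 9, 11 and 12.

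Gene ends held fewer peaks than their surroundings in replicate 1 and more in replicate 2. In replicate 1, 4.39% of peaks touched the end of a protein-coding gene, against 4.70% after chromosome-wide shifts and 4.69% after local shifts, and the share lay below all 1000 shifts of both kinds (one-sided permutation test for a lower share, p = 0.000999). In replicate 2, 5.44% of peaks did, against 4.40% and 5.06% (one-sided permutation test for a higher share, p = 0.000999 each). Coverage at positions 500 bp outside a gene was 15.4% in replicate 1, where it averaged 18.1% beyond 10 kb. At 500 bp inside a gene it was 14.7% in replicate 2, where it averaged 12.2% beyond 10 kb. In replicate 1 the lower share was not seen among its peaks with a −log10 p of at least 2, where the ratio to chromosome-wide chance was 1.12 (one-sided permutation test for a higher share, p = 0.0896).

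**Figure D2:**
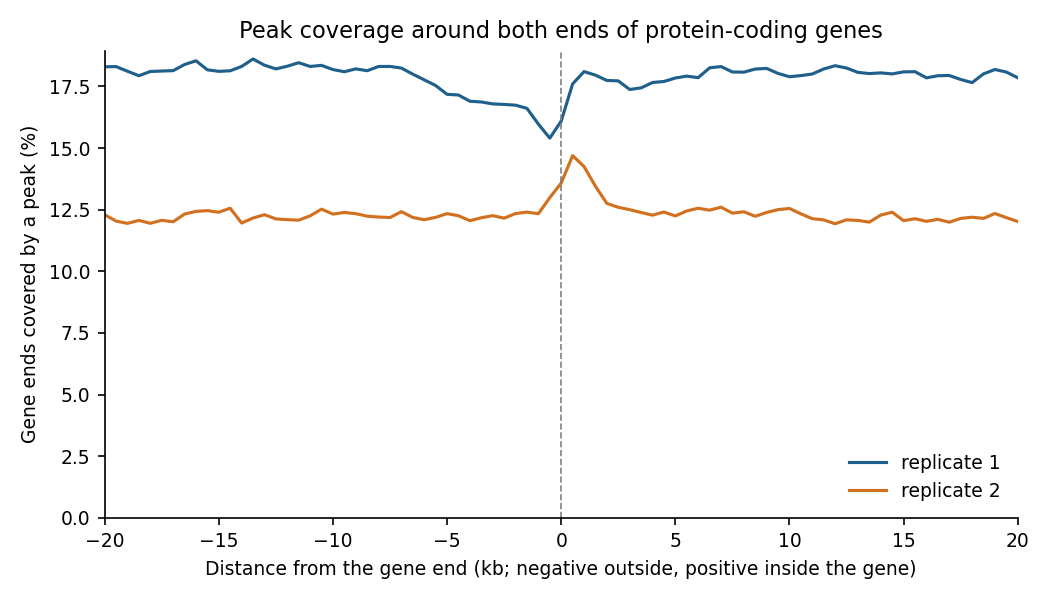
Share of the ends of protein-coding genes covered by a peak (%), by distance from the end (kb, negative outside the gene and positive inside), both ends of each gene pooled, for each replicate. Replicate 1 dips to 15.4% just outside genes and replicate 2 rises to 14.7% just inside them.

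A peak at a gene end in both replicates was found for 7419 of the 21627 protein-coding genes (34.3%), and 5236 genes had one in neither. Replicate 1 had a peak at 12879 genes and replicate 2 at 10931. The count for both replicates was 1.14 times the mean of the chromosome-wide shifts, 6528 (one-sided permutation test, p = 0.000999). It did not exceed the local shifts, which gave a mean of 7425 and a range of 7213 to 7642 (permutation test, p = 0.544).

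Mcrs1 itself (chromosome 15, 99242817 to 99251961) had a peak at its lower end in both replicates, with folds of 1.58 and 1.74. The class I genes H2-K1 (chromosome 17, 33996012 to 34000619) and H2-D1 (chromosome 17, 35263094 to 35267497) had peaks in both, with folds of 1.68 and 1.74 and of 1.69 and 1.74. The peptide transporter genes Tap1 and Tap2 had folds of 1.63 and 1.66 and of 1.63 and 1.62, and the immunoproteasome genes Psmb8 and Psmb9 had 1.63 and 1.66 and 1.63 and 1.73. These neighbouring genes are not independent, since some of the folds come from the same peak. In replicate 1 a peak was common to Tap1 and Psmb9 and another to Tap2 and Psmb8, and in replicate 2 a peak was common to Tap1 and Psmb8. For each of these genes the folds of the replicates came from opposite gene ends. Nlrc5 (chromosome 8, 94434335 to 94527272), the transactivator of class I genes, had the highest fold of the 12 preset genes in replicate 2, 1.96, and 1.55 in replicate 1. B2m, Tapbp, Irf1 and Yy1 had a peak in replicate 2 only, with folds of 1.74, 1.88, 1.76 and 1.89. Thus 8 of the 12 preset genes had a peak in both replicates, against a mean of 6.26 and a range of 1 to 10 in 200 local shifts (one-sided permutation test, p = 0.234). The count depended on the window: 4 of the 12 had a peak in both replicates with windows of 500 bp, where H2-K1, H2-D1, Tap2 and Psmb9 lost it in 1 replicate, and 11 with 3000 bp (local shifts gave means of 4.28 and 9.95, permutation p = 0.672 and 0.383). At 6 of the 8 genes, all but Psmb9 and Nlrc5, the peaks of the replicates were shared by position, and at Tap1 and Psmb8 this was the same pair of peaks. None of the peaks at the 12 genes had a −log10 q above 0.

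**Figure D3:**
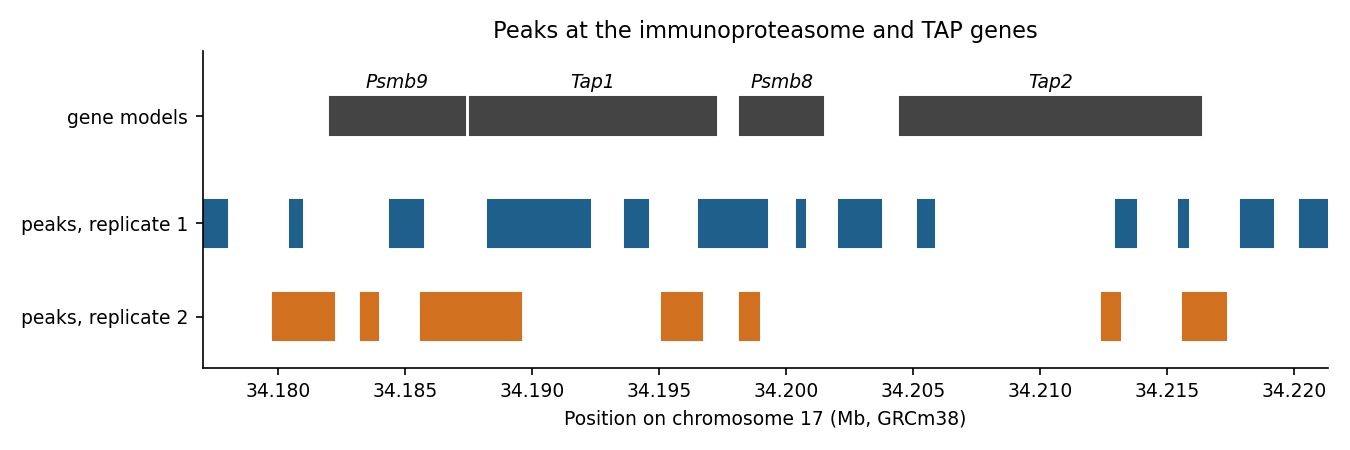
Map of chromosome 17 from 34.177 to 34.221 Mb (GRCm38), with the gene models of Psmb9, Tap1, Psmb8 and Tap2 (grey) and the MCRS1 peaks of replicate 1 (blue) and replicate 2 (orange). Replicate 1 has 13 peaks covering 36.8% of the region and replicate 2 has 7 covering 26.4%.

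The 10 genes of highest mean fold percentile were led by Setd5, a chromatin regulator (chromosome 6, 113077262 to 113153432), with folds of 1.92 and 2.13. Next came Mrs2, a mitochondrial magnesium channel (1.90 and 2.06), Cpa3, a mast cell carboxypeptidase (2.07 and 1.97), and Stxbp2 (2.03 and 1.97). Tubb3, a neuronal tubulin, had 1.84 and 2.19, Zfp282 had 1.84 and 2.14, Casc3 had 1.89 and 2.01, Gstm6 had 1.98 and 1.96, Sphk1, a sphingosine kinase, had 1.85 and 2.07, and Sgk2 had 1.92 and 1.97. None of them belongs to the antigen presentation lists. Whether any gene ranked higher than unrelated lists would place it was not tested. Peak coverage within 500 kb of these genes ran from 4.69% at Mrs2 to 52.0% at Stxbp2.

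Among the genes of T cell recognition, no list differed detectably from other genes in its share with a peak in both replicates. Of 20 genes of class I presentation 10 had one (50%, odds ratio 1.92, Fisher's exact test, adjusted p = 0.490), where local shifts gave a mean of 9.50. H2-D1, H2-K1 and Psmb9 ranked highest, and Erap1, H2-Q4 and Pdia3 had no peak in either replicate. In replicate 2 alone 16 of the 20 class I genes had a peak (odds ratio 3.59, Fisher's exact test, adjusted p = 0.120). Local shifts gave a mean of 13.1 there and a range of 7 to 19 (two-sided permutation test, adjusted p = 0.585). In replicate 1 alone 11 had one (odds ratio 0.822, Fisher's exact test, adjusted p = 0.936), against a local mean of 13.7. With windows of 500 bp the odds ratio for both replicates was 0.710. Interferon-stimulated genes had a peak in 15 of 28 cases (53.6%, odds ratio 2.201, Fisher's exact p = 0.0444, adjusted p = 0.229), against a mean of 13.7 after local shifts. Gbp3, Ifi35 and Gbp7 ranked highest there, and Ifih1, Usp18 and Xaf1 had none. Among class I regulators and interferon signalling genes 10 of 25 had a peak in both (Fisher's exact test, adjusted p = 0.860), with Tyk2, Rfxap and Socs1 highest and Ifngr1 and Stat2 without a peak. Coverage within 500 kb was 42.0%, 34.1% and 20.6% around Tyk2, Rfxap and Socs1, and 5.26% and 4.71% around Ifngr1 and Stat2. The counts were 5 of 11 for class II presentation (adjusted p = 0.860), 5 of 13 for chemokines of T cell recruitment (adjusted p = 0.921), and 3 of 16 for checkpoint ligands and death receptors (adjusted p = 0.771, Fisher's exact test).

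The lists holding partners of MCRS1 did not stand apart either. Of the INO80 complex, a list that includes Mcrs1, 4 of 15 genes had a peak in both replicates (Fisher's exact test, adjusted p = 0.921). Among them were Mcrs1 itself, Actl6a and Tfpt, and Ino80 had none in either. Of the NSL and MSL complexes 5 of 11 had one (Fisher's exact test, adjusted p = 0.860), with Hcfc1, Wdr5 and Kansl1 highest, and Kat8 and Msl2 had none. Peak coverage within 500 kb was 4.83% around Ino80, 6.20% around Kat8 and 5.74% around Msl2. It was 37.2% around Actl6a, 24.4% around Hcfc1 and 35.3% around Kansl1, but 6.01% around Tfpt and 7.11% around Wdr5.

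The lists that differed from other genes by Fisher's exact test were large gene families lying in clusters. None of the 58 histone genes had a peak in both replicates (odds ratio 0.0163, Fisher's exact test, adjusted p = 8.00e-10), 129 of 1106 olfactory receptor genes had one (11.7%, odds ratio 0.240, adjusted p = 1.97e-68), and 82 of 353 vomeronasal receptor genes (23.2%, odds ratio 0.577, adjusted p = 8.91e-05). Defensins, antimicrobial peptides encoded largely on chromosome 8, were higher, at 42 of 72 (58.3%, odds ratio 2.68, Fisher's exact test, adjusted p = 0.00029), with Defa41, Defb8 and Defb4 highest. The local shifts gave counts close to those observed for 3 of these lists, with means of 138 olfactory receptors, 81.8 vomeronasal receptors and 41.0 defensins (two-sided permutation test, adjusted p = 0.896, 1.00 and 1.00). For histone genes they gave a mean of 6.10 and a range of 0 to 17 against the 0 observed (two-sided permutation test, p = 0.00799, adjusted p = 0.296). This test does not exclude a lower count of histone genes, since no count is lower than 0, and the smallest two-sided p of 1000 shifts, 0.002, does not let a single list pass after adjustment over 37. Against random lists matched on local peak coverage, only the histone genes remained lower, with 12.9% expected (permutation test, adjusted p = 0.00740). Those random lists were not matched on clustering. This p thus treats histone genes that share a cluster as independent, which the local shifts do not. In replicate 2 alone the calls of histone genes (23 of 58, odds ratio 0.647, Fisher's exact test, adjusted p = 0.302) and defensins (47 of 72, odds ratio 1.83, adjusted p = 0.120) were lost, and in replicate 1 alone that of vomeronasal receptors (191 of 353, odds ratio 0.797, adjusted p = 0.143).

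**Figure D4:**
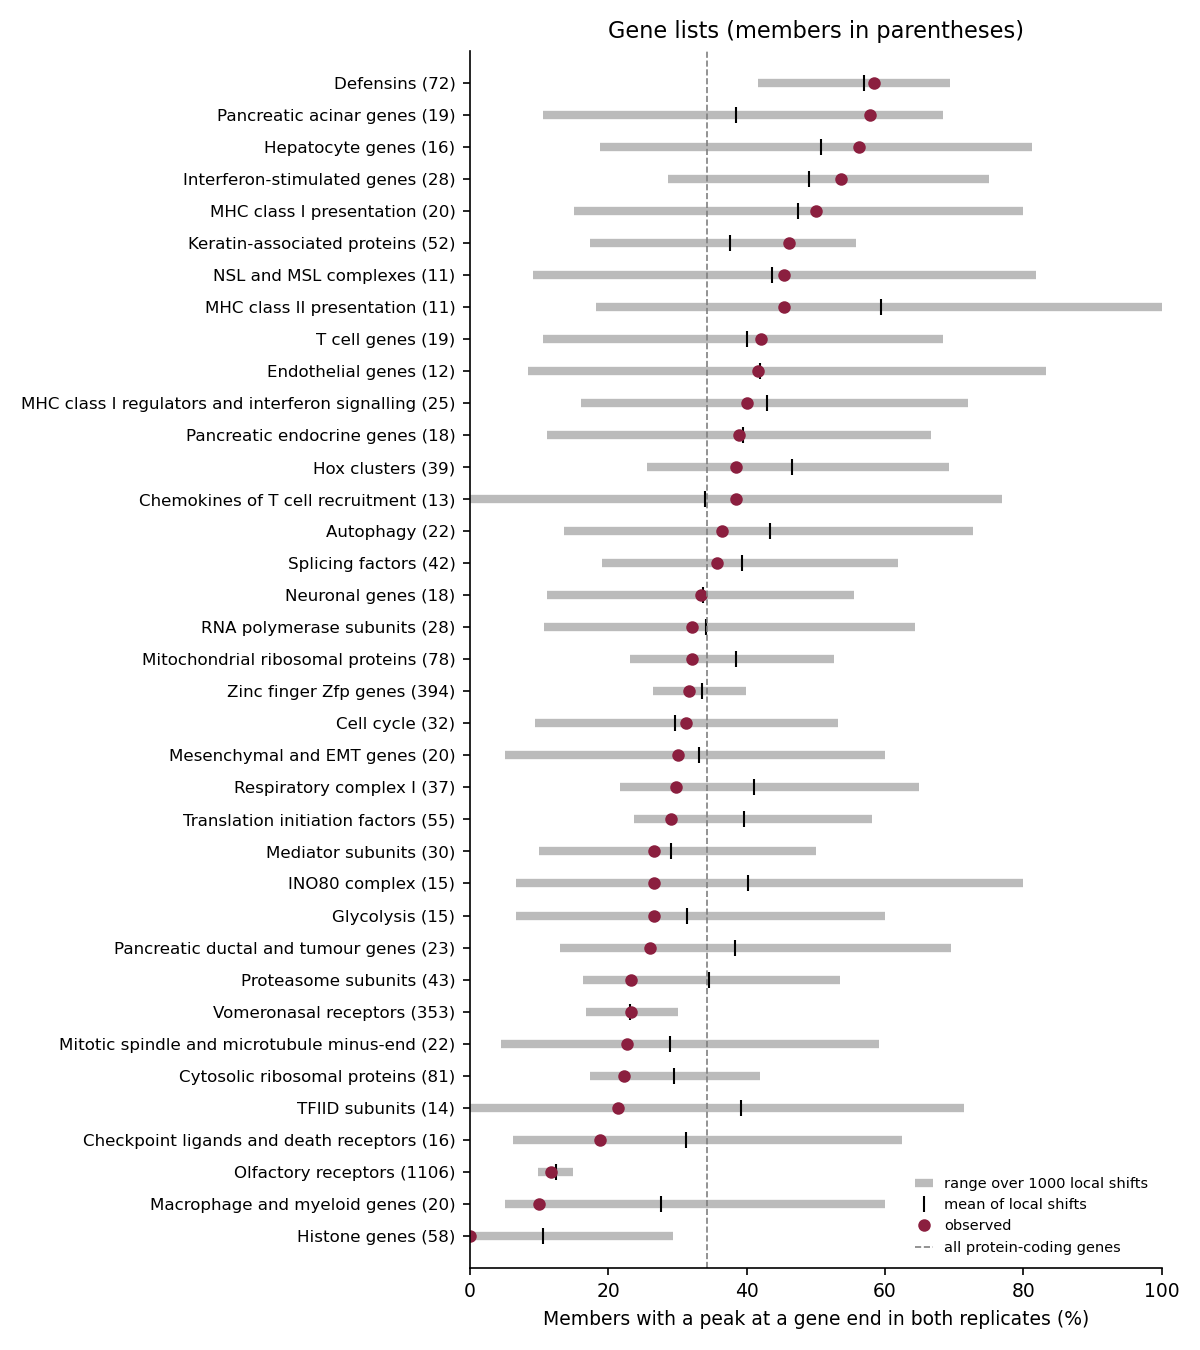
Share of each of the 37 gene lists with a peak at a gene end in both replicates (%, points), with the range (grey bars) and mean (ticks) of 1000 local shifts and the share of all protein-coding genes (dashed line, 34.3%). The extremes are defensins at 58.3% and histone genes at 0%, and every point lies within its grey bar.

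Of the tissue markers, acinar genes of the pancreas had a peak in both replicates in 11 of 19 cases (57.9%, Fisher's exact adjusted p = 0.229), with Rbpjl and Amy2b among the highest and Gp2 and Ptf1a without any. Ductal and tumour genes had 6 of 23 (Fisher's exact test, adjusted p = 0.860), with Sox9, Yap1 and Krt7 highest and Cdkn2a, Cldn4 and Cldn7 without any, and endocrine genes 7 of 18 (adjusted p = 0.921). Peak coverage within 500 kb was 23.9% and 25.9% around Rbpjl and Amy2b, and 6.69% and 4.78% around Gp2 and Ptf1a. It was 36.4%, 37.4% and 23.1% around Sox9, Yap1 and Krt7, and 2.60%, 16.1% and 6.78% around Cdkn2a, Cldn4 and Cldn7. Macrophage and myeloid genes had 2 of 20, Fcgr3 and Lyz2 (odds ratio 0.259, Fisher's exact test, adjusted p = 0.189). T cell genes had 8 of 19 (adjusted p = 0.860), endothelial genes 5 of 12 (0.863), neuronal genes 6 of 18 (1.00), hepatocyte genes 9 of 16 (0.407), and mesenchymal genes 6 of 20 (0.921), all adjusted p by Fisher's exact test.

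Housekeeping and process lists gave the following counts with a peak in both replicates, none past the threshold after adjustment. Cytosolic ribosomal proteins had 18 of 81 (odds ratio 0.557, Fisher's exact adjusted p = 0.187), mitochondrial ribosomal proteins 25 of 78 (0.921), respiratory complex I 11 of 37 (0.874), proteasome subunits 10 of 43 (0.490), and translation initiation factors 16 of 55 (0.860). RNA polymerase subunits had 9 of 28 (1.00), Mediator 8 of 30 (0.860), TFIID 3 of 14 (0.860), and splicing factors 15 of 42 (0.921). Glycolysis had 4 of 15 (0.921), cell cycle 10 of 32 (0.921), autophagy 8 of 22 (0.921), and mitotic spindle genes 5 of 22 (0.860). Zinc finger genes had 125 of 394 (0.771), Hox clusters 15 of 39 (0.874), and keratin-associated proteins 24 of 52 (0.327).

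Taken singly, replicate 1 had fewer peaks than local chance at 5 lists, and replicate 2 differed from it detectably at none. In replicate 1, 29 of the 81 cytosolic ribosomal protein genes had a peak, against 46.3 expected, and 14 of 37 complex I genes, against 24.1. Translation initiation factors had 25 of 55 against 37.1, histone genes 3 of 58 against 17.8, and ductal and tumour genes 7 of 23 against 14.03 (two-sided permutation test with local shifts, adjusted p = 0.0148 for each). In replicate 2 the same lists had 45, 24, 36, 23 and 15 members with a peak, against 36.6, 21.8, 29.5, 16.0 and 13.5 expected (adjusted p from 0.538 to 0.985). The difference between the replicates was not tested for these lists.

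Fold ranks separated few lists, and the random sets were not matched on local peak coverage. Glycolysis genes with a peak in both replicates, 4 genes including Pfkm, Pfkl and Pkm, had a median percentile of 17.7, against 52.9 for random sets (permutation test, adjusted p = 0.0420 over 35 lists), and Gapdh and Eno1 had no peak in either replicate. Pfkm stood at 65.3, above the random sets. Pfkl and Pkm stood at 19.8 and 15.6, in neighbourhoods with peak coverage of 6.60% and 4.81%. The 129 olfactory receptor genes had a median of 43.8 against 53.0 (permutation test, adjusted p = 0.0140). Neither call held in both replicates taken alone: for glycolysis the adjusted p was 0.114 in replicate 1 and 0.738 in replicate 2, and for olfactory receptors 0.00700 and 0.738 (permutation tests). Other lists passed in 1 replicate alone: cytosolic ribosomal proteins in replicate 1, with a median percentile of 27.3, and ductal and tumour genes (92.6) and zinc finger genes (37.9) in replicate 2 (permutation tests, adjusted p = 0.0490 each). Ranked by summed peak length, neither list passed (adjusted p = 0.222 and 0.422), and keratin-associated protein genes did, with a median percentile of 75.8 (permutation test, adjusted p = 0.0140). Class I presentation genes had a median of 45.2 against 52.9 (permutation test, adjusted p = 0.779).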

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

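The tests of fold in this part were chosen after the peaks had been seen. Peaks outside the chromosomes used were found in each list, with no control values to set them against. Replicate 1 had 152 peaks on chromosome Y, covering 135 kb with a median fold of 1.59 and none with a −log10 q of at least 1, and replicate 2 had none there. Replicate 2 had 24 peaks on unplaced scaffolds, and replicate 1 had none. Of these, 17 lay on a single scaffold, covering 72.4 kb with a median fold of 1.22, and 10 of them had a −log10 q of at least 1.

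The peaks that passed the caller's q lay largely in a few repeated regions. In replicate 2, 8 of the 30 such peaks lay at the start of chromosome 9 near Mir101c, 10 on that scaffold, and 1 over the 18S ribosomal RNA pseudogene Rn18s-rs5 on chromosome 17. In replicate 1, 3 of 10 lay at the Rn18s-rs5 locus, 3 at the start of chromosome 11 around Sfi1, and 1 at the start of chromosome 9. One explanation is very deep coverage of multi-copy sequence, where a small fold reaches a low q. In these regions, the median fold of the 19 peaks of replicate 2 stood at percentile 0.00664 of all its peaks. All 19 lay below the median, the predicted direction. However, the peaks were picked for a low q, so a small fold among them restates the explanation and does not test it. Read depth is unknown, and neighbouring peaks are not independent. The 7 peaks of replicate 1 stood at percentile 20.6, but only 4 lay below the median. The explanation stays open in both replicates. The 11 other peaks of replicate 2 had a median fold of 1.67 and the 3 other peaks of replicate 1 had 2.56, and neither was part of this test. No biological explanation was tested, since the design has a single immunoprecipitated group.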

How the results depend on the processing

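Limits on −log10 p, ranks by −log10 p, windows on both gene ends, local shifts for gene ends, genes and lists, and lists matched on local peak coverage were chosen after seeing the data, and the other settings before. The excess of shared peaks kept its direction and its side of the threshold under the 5 alternatives that gave a value, with ratios of 1.11 to 6.23 in replicate 1 and 1.11 to 6.22 in replicate 2. Of the other results, the cause of each move was not tested unless the setting itself leaves fewer peaks or genes. With a −log10 q of at least 2, 6 peaks (0.00778 Mb) of replicate 1 and 26 (0.0362 Mb) of replicate 2 were left, and with at least 5, 3 (0.00118 Mb) and 18 (0.0252 Mb). A fold of at least 3 left 1 peak (0.000419 Mb) and 0 (0 Mb), and a −log10 p of at least 2 left 2816 (2.76 Mb) and 6080 (5.44 Mb). Genes with a peak in both replicates fell from 7419 to 0 under the q and fold limits, 6 under the p limit and 68 with the 20000 peaks of highest fold, and numbered 4749 with windows of 500 bp and 13135 with 3000 bp. With 1 replicate left out, they numbered 10931 to 12879. Gene lists above and below the other genes, 1 and 3 with all peaks, were 0 and 0 under each of these 5 limits, since few genes were left, and 2 lists were above with windows of 500 bp. With 1 replicate left out, 0 to 2 lists were above. Matched random lists left 0 above and 1 below, and local shifts left 0 and 0, where 1000 shifts do not let a single list pass and histone genes still had 0 against 6.10. The ratio of peaks at gene ends to chance in replicate 1, 0.935, turned to 1.00 with the 20000 peaks of highest fold (permutation p = 0.522), 1.12 with the p limit, 1.02 with the p limit and local shifts (permutation p = 0.383), and 1.00 with shared peaks only (permutation p = 0.502). With the 20000 peaks and local shifts it was 0.915. In replicate 2 it went from 1.24 to 1.08 with a −log10 q of at least 2 (permutation p = 0.522) and 0 with at least 5. The ratio for genes in both replicates, 1.14, was 2.703 with the p limit (6 genes, permutation p = 0.0448), 1.24 with the 20000 peaks (permutation p = 0.0547) and 0.999 with local shifts. The odds ratio of class I presentation, 1.92, was 0.710 with windows of 500 bp, 0.951 with 3000 bp, and 0.822 to 3.59 with 1 replicate left out. That of vomeronasal receptors turned from 0.577 to 1.00 against local shifts, and that of histone genes to 2.68 with the 20000 peaks, where no member had a peak. Ranking by summed peak length put 1 list past the threshold, not 2, and a different one. Peaks with a −log10 p of 2 or more, or a fold of 3 or more, left none of the 12 preset genes with a peak. The overlap ratio was not run for the q and fold limits, nor density for a −log10 q of 5, for want of peaks. Any annotated transcript start, CpG matching, motif tests and a rank by −log10 q were not run. Depth is unknown, and the small number of peaks past a q limit bounds each gene-level call. No paired analysis was possible because a single group had peak lists.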

Other observations

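The tests in this part were chosen after the results they bear on had been seen, except those of gene content and of shared peaks at gene ends, which were written before. Of 8 kinds of gene other than those annotated as protein-coding, 4 differed from local shifts in how often both replicates had a peak at an end, and the kinds were not compared with each other. Pseudogenes did in 2594 of 9852 cases (26.3%, against 23.4% after local shifts, two-sided permutation test with 200 shifts, adjusted p = 0.0299 over 9 kinds of gene). Genes of small nucleolar RNAs, which guide RNA modification, did in 252 of 1340 (18.8% against 15.7%, permutation test, adjusted p = 0.0299), and microRNA genes in 261 of 1228 (21.3% against 17.9%, adjusted p = 0.0448). Genes of small nuclear RNAs, the RNA parts of the spliceosome and their many copies, were lower, at 141 of 1003 (14.1% against 16.8%, permutation test, adjusted p = 0.0299). Long non-coding RNA genes had 34.7% against 34.5% (adjusted p = 0.649), transfer RNA genes 15.7% against 18.3% (adjusted p = 0.358), ribosomal RNA genes 27.0% against 16.9% (adjusted p = 0.358), and V segments of antigen receptors 19.3% against 20.9% (adjusted p = 0.576, permutation tests). None of these 4 calls held in both replicates taken alone. The adjusted p in replicates 1 and 2 was 0.0299 and 0.0537 for pseudogenes, 0.343 and 0.0448 for small nucleolar RNAs, 0.965 and 0.0640 for microRNAs, and 0.384 and 0.0537 for small nuclear RNAs (permutation tests). In replicate 1 alone, transfer RNA genes had a peak in 114 of 408 cases, 27.9% against 42.1% (adjusted p = 0.0299, permutation test), and in replicate 2 alone in 158, 38.7% against 33.8% (adjusted p = 0.0672).

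The 74 peaks shared at a −log10 p of at least 2 lay at 49 loci, counting peaks within 1 Mb as a locus, and 35 of them lay at 10 loci with several such peaks. All of these loci were chosen after their values were seen. The largest, with 10 peaks, ran from 19.9 to 20.8 Mb on chromosome 8, beside the defensin region and next to pseudogenes such as Gm20778. Another 6 lay around Sfi1 and Pisd-ps1 on chromosome 11 near 3.13 Mb, 3 in the imprinted non-coding gene Snhg14 on chromosome 7 (59.7 Mb), and 3 at Rn18s-rs5 on chromosome 17 (39.84 Mb). Among the 39 that lay alone were peaks inside Shox2, Zfhx3, Dgkb, Rnf150 and Il1rapl1.

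Peak density changed in steps of many Mb along chromosomes, at the same places in both replicates. Gene content is argued against as the cause, since protein-coding genes per Mb explained 2.58% of the variance of the coverage of replicate 2. Dosage of chromosome segments in the cell line, where extra copies give more reads and more regions past a lenient p, may be the cause, as segments drawn from replicate 1 explained 76.4% of that variance. The same value would come from wide chromatin domains or from a common input, so these stay open, and copy number was not measured here. The 76.4% also includes differences between whole chromosomes, and no share within chromosomes is given here. Within segments, coverage correlated across bins with gene number at r = 0.475 in replicate 2 and 0.0516 in replicate 1, and the replicates with each other at r = 0.304, bins not being independent.

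Gene ends held fewer peaks than their surroundings in replicate 1 and more in replicate 2. Dosage is argued against as the whole cause of the excess in replicate 2, which fell from 1.24 times chance with chromosome-wide shifts to 1.07 times with shifts that stay within 100 kb and was still above all 1000 of these. Most of the chromosome-wide excess thus went with regional density. MCRS1 bound at gene ends in both replicates would not by itself give the 0.938 times local chance of replicate 1, but this value is part of the pattern and does not exclude it. With local shifts, replicate 1 had 1.02 times chance among its peaks with a −log10 p of at least 2 (permutation p = 0.383) and 0.915 times among its 20000 peaks of highest fold (permutation test for a lower share, p = 0.00995), so such binding stays open. A library difference in the recovery of open or CpG-rich promoter DNA was not decided either. At 408 genes of 9 housekeeping families, replicate 1 had 0.727 times the local chance (45.1% of genes against 62.1%, permutation test, p = 0.002) and replicate 2 had 57.8% against 51.8% (p = 0.00799). Some of these families had already been seen to be low in replicate 1, so this restates the pattern and does not support the explanation. The share of replicate 2 also lay within the range of the 1000 shifts, which reached 58.6%, and base composition was not measured, so this stays open, as does binding in replicate 2 alone.

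One hypothesis was that the excess of shared peaks over local chance comes from binding at gene ends. Among replicate 1 peaks, the shared number was 1.110 times the local chance at gene ends and 1.107 times elsewhere. The difference of 0.00321 lay within the spread of the shifts (two-sided permutation test, p = 0.781), so the test gave no support to the hypothesis and did not exclude a small part of it.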
